A study of Mus musculus with 12 samples.

How the data were processed

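The series holds 12 poly(A) RNA-seq libraries from liver and gastrocnemius of 6 female mice, 3 wild type and 3 homozygous for Mars2 R135W, and every library was used. Per the file headers, each file gives raw counts: the authors counted fragments over the exons of each gene symbol of the UCSC mm10 annotation with featureCounts 1.5.2, as read pairs, without a strand option, with primary alignments only, and with a fragment that overlaps several genes counted for each of them. Reads had been aligned with STAR 2.4.0, per the submitters' processing notes. The deposited counts carry no normalisation, and replicates were not pooled. The 12 files list the same 24062 genes in the same order.

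Counting a fragment for every gene it overlaps gives genes with shared exons shared counts. Among the tested genes 69, in 32 sets, have identical counts in all libraries, of which 8 were called in liver and 4 in gastrocnemius; named genes with shared exons are marked in the text. A fragment from a repeated sequence is counted once, at its primary alignment, so recent paralogs share it by the aligner's choice. Positions are those of the file's annotation (mm10). Genes of mitochondrial DNA were not analysed here.

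Total counts ran from 20751583 to 30460237 per library. Replicate libraries were compared by chi-squared per degree of freedom over genes with at least 10 counts in the pair, and the differences exceeded counting error in every pair of separate animals. This does not show how far depth limits genes with few counts.

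Genotype was tested within each tissue on its 6 libraries with R 4.3.3 and edgeR 4.0.16: TMM factors, filterByExpr by group, quasi-likelihood F test of R135W against WT, Benjamini-Hochberg adjustment over all tested genes, threshold at an adjusted p of 0.05. SE is the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. The difference between tissues was the interaction of genotype and tissue in a fit of all 12 libraries in 4 groups. Animal numbers in the labels pair each liver with a muscle library, so the fit was run again with the animal as a block. The counts themselves do not settle this pairing. Each animal's deviation from its group mean correlated between its liver and its muscle library at 0.00189 to 0.0841, weak but all positive. For libraries of different animals of a genotype the correlations were -0.0971 to 0.0771. Deviations within a group cancel out, so these values depend on each other. No covariate was used; the labels give ages but no batch, litter or time of day.

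Gene lists, 47 of pathways and 19 of cell type markers, were written before the data were examined, as were the tests, the alternatives and the rule for named genes. A list needed 5 tested members. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Members are counted past the threshold over all genes and with adjustment over the list alone. Camera with an estimated correlation and fry were run beside it. Of the lists, 2, the mitochondrial DNA encoded proteins and the pancreatic acinar markers, had too few tested members in every comparison.

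The rule for named genes took Mars2 first. It then took up to 10 genes per direction with the largest change among called genes whose libraries were fully apart, with at least 1 CPM in a group and a proper gene name. From each list it took up to 4 called members with the smallest p, or up to 2 where none passed, and for the difference between tissues the 10 named genes with the smallest adjusted p. Genes the rule picked that passed no test are printed only in part. Genes named as shared between tissues outside this rule (Apol9a, H2-D1, H2-T23, Ifit2, Rtp4, Sec24a and Uba7) were chosen after their values were seen.

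Overlap between tissues was counted among genes tested in both fits and compared with independent lists by Fisher's exact test, two-sided. Genes within 5 Mb of Mars2 were compared with all others in the same way. Contrasts between lists and the clock correlation used permutations of the list members with a fixed seed. Genes of a list vary together between animals, so these p-values overstate the evidence that 6 animals give. The 10 splits of the 6 animals into 3 and 3 were each fitted as the real one was.

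Alternatives tried were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, age as a covariate, a fit of all 12 libraries, a minimum change of 2-fold, an unadjusted threshold for the overlap, windows of 2 and 20 Mb, the animal block, and leaving out each library or animal in turn. Chosen after seeing the data were leaving out the gastrocnemius library of animal 12 for the difference between tissues, and testing its lists over genes tested in both tissues.

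The tests were checked on simulated data with 100 genes changed 2-fold and 100 changed 4-fold among the series' own levels and spread. The liver test recovered 71% and 98% of them with 8.65% false calls, the gastrocnemius test 92% and 100% with 5.88%, the difference test 61% and 98% with 5.36%, and the blocked difference test 60% and 97% with 9.25%. All 4 false shares lie above the nominal 5%. In the simulated tissue fits camera called a list of 30 genes raised 2-fold and 0 of 200 random lists, also without adjustment; simulated genes vary independently, unlike real ones. Figures were drawn with matplotlib 3.10.9.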

Results

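RNA was sequenced from 12 libraries: liver and gastrocnemius, a calf muscle, of the same 6 female C57BL/6N mice. Of these animals, 3 were wild type (WT) and 3 were homozygous for R135W, a missense change in Mars2, the nuclear gene for the synthetase that charges the mitochondrial methionine tRNA. The libraries fall into 4 groups of 3: liver WT and gastrocnemius WT (animals 6, 8 and 9), and liver R135W and gastrocnemius R135W (animals 5, 7 and 12). Animals were 7.4 to 9.0 weeks old in both genotypes. Total counts per library ran from 20751583 to 26275128 in liver WT, from 21513860 to 30460237 in liver R135W, from 23992591 to 28669346 in gastrocnemius WT and from 23895670 to 28480863 in gastrocnemius R135W. Replicates differed by more than counting error: chi-squared per degree of freedom between library pairs of a group was 41.7 to 118 in liver and 8.07 to 17.8 in muscle. Levels are given as CPM, counts scaled to the size of the library, as mean ± SD with n = 3 per group. All changes are log2 fold changes of R135W minus WT unless stated. An SE follows a fold change where one is given.

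The gene that carries the variant was looked at first. Mars2 lies on chromosome 1 from 55237177 to 55240058 (mm10) and is annotated as a single exon. Its RNA level in liver was 2.77 ± 0.627 CPM in WT and 2.93 ± 0.646 CPM in R135W, a log2 fold change of 0.08 (SE 0.25, adjusted p = 0.90), which did not hold up against the spread between animals. In gastrocnemius it was 11.7 ± 0.941 CPM in WT and 9.45 ± 0.961 CPM in R135W, a log2 fold change of -0.31 (SE 0.11). By edgeR's test the p was 0.0161 unadjusted and 0.295 adjusted over all tested genes. All 3 R135W animals lay below all 3 WT animals, a separation that chance gives in 10% of genes. The liver values rest on 48 to 120 counts per library and the muscle values on 232 to 314.

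In liver, the question was which genes differ between R135W and WT animals. Interferon-stimulated genes rose together, with 40 of 55 measured members past the test and a list median of 1.26. Irf7, the transcription factor that amplifies type I interferon production, rose from 50.3 ± 3.82 to 287 ± 66.3 CPM. Macrophage markers rose beside them, with 13 of 17 members past the test, among them the scavenger receptor gene Marco at 2.12 (SE 0.24). Lower in R135W was the steroid hydroxylase gene Cyp17a1, at -2.54 (SE 0.53). By edgeR's quasi-likelihood test, 457 of 13935 genes passed an adjusted p of 0.05, 384 higher and 73 lower in R135W, and 263 of them changed at least 2-fold (235 higher, 28 lower). The 3 R135W libraries lay entirely above or below the 3 WT libraries for all 457, where 23.7% of tested genes separated in this way and chance gives 10%. At an unadjusted p under 0.05 stood 2449 of the 13935 genes, the background for unadjusted counts within lists.

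Of the 10 largest rises in liver among named genes of at least 1 CPM in a group, 7 belong to the interferon-stimulated list. Oas1g rose by 3.27 (SE 0.30), from 3.51 ± 0.676 to 34.0 ± 12.4 CPM, and Oas1a by 3.23 (SE 0.26, adjusted p = 0.00242); both encode oligoadenylate synthetases, which activate RNase L on double-stranded RNA. The interferon-inducible Ifi44 rose by 3.07 (SE 0.36), the viperin gene Rsad2 by 2.70 (SE 0.39), the influenza-resistance GTPase gene Mx1 by 2.50 (SE 0.35) and the synthetase-like Oasl2 by 2.38 (SE 0.30). Ly6a, the gene of the surface antigen Sca-1, rose by 2.93 (SE 0.48), with an SD of 70.5 CPM around a mean of 95.1 CPM in R135W. Cdc20, an activator of the anaphase-promoting complex, rose by 3.05 (SE 0.57) and Dnah1, an axonemal dynein heavy chain, by 3.17 (SE 0.42), both from low levels of 0.366 and 0.153 CPM in WT.

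The largest falls in liver were chosen in the same way. Cyp17a1 fell to 25.5 ± 12.0 CPM, with WT animals far apart around a mean of 149 CPM, the sulfotransferase Sult3a1 from 96.6 ± 20.8 to 25.1 ± 13.6 CPM, and the retinoic acid hydroxylase Cyp26a1 from 38.7 ± 20.8 to 11.4 ± 3.50 CPM. Acot3, a peroxisomal acyl-CoA thioesterase, changed by -1.40 (SE 0.24) and the zinc transporter Slc39a5 by -1.39 (SE 0.30). Rgs16, a regulator of G protein signalling, fell to 203 ± 78.4 CPM from a mean of 575 CPM. Bhlhe41, a repressor of the circadian clock, changed by -1.83 (SE 0.40), and Camk4, a calcium/calmodulin-dependent kinase, by -1.46 (SE 0.20). Cd207, the gene of the lectin langerin, fell from 2.07 ± 0.523 to 0.615 ± 0.0126 CPM and Unc79, a cation channel partner, changed by -2.34 (SE 0.48).

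Among the 66 gene lists, camera with its preset correlation called 22 of the 59 that could be tested in liver, 15 higher and 7 lower. With a correlation estimated per list none of the 22 held: 0 passed after adjustment and 8 at an unadjusted p under 0.05. The rotation test fry called 10, of which 9 were among the 22. For interferon-stimulated genes, 40 of 55 rose over all genes and 52 when adjusted over the list alone (adjusted p = 0.0824 with an estimated correlation). Ifi27 rose by 1.91 (SE 0.12) and Ifi27l2a by 1.70 (SE 0.11); 9.78% and 11.7% of their exon lengths overlap each other. In the list of guanylate binding proteins and immunity related GTPases, which act against intracellular pathogens, 11 of 22 rose, and 18 adjusted over the list alone (adjusted p = 0.335 with an estimated correlation). Its members Cxcl10, a chemokine for T cells, and Gbp3 rose by 2.09 (SE 0.26) and 1.98 (SE 0.30), and Gvin1, which shares 100% of its exons with Gm4070, by 2.10 (SE 0.27). The GTPase gene Ifi47 changed by 1.24 (SE 0.19). Among cytosolic nucleic acid sensing genes 9 of 25 rose, and 17 adjusted over the list alone (adjusted p = 0.142 with an estimated correlation). They include Zbp1, a sensor of Z-form nucleic acid, at 1.99 (SE 0.20), the RIG-I-like receptor gene Dhx58 at 1.53 (SE 0.16) and the RNA-editing enzyme gene Adar at 0.83 (SE 0.11).

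**Figure D1:**
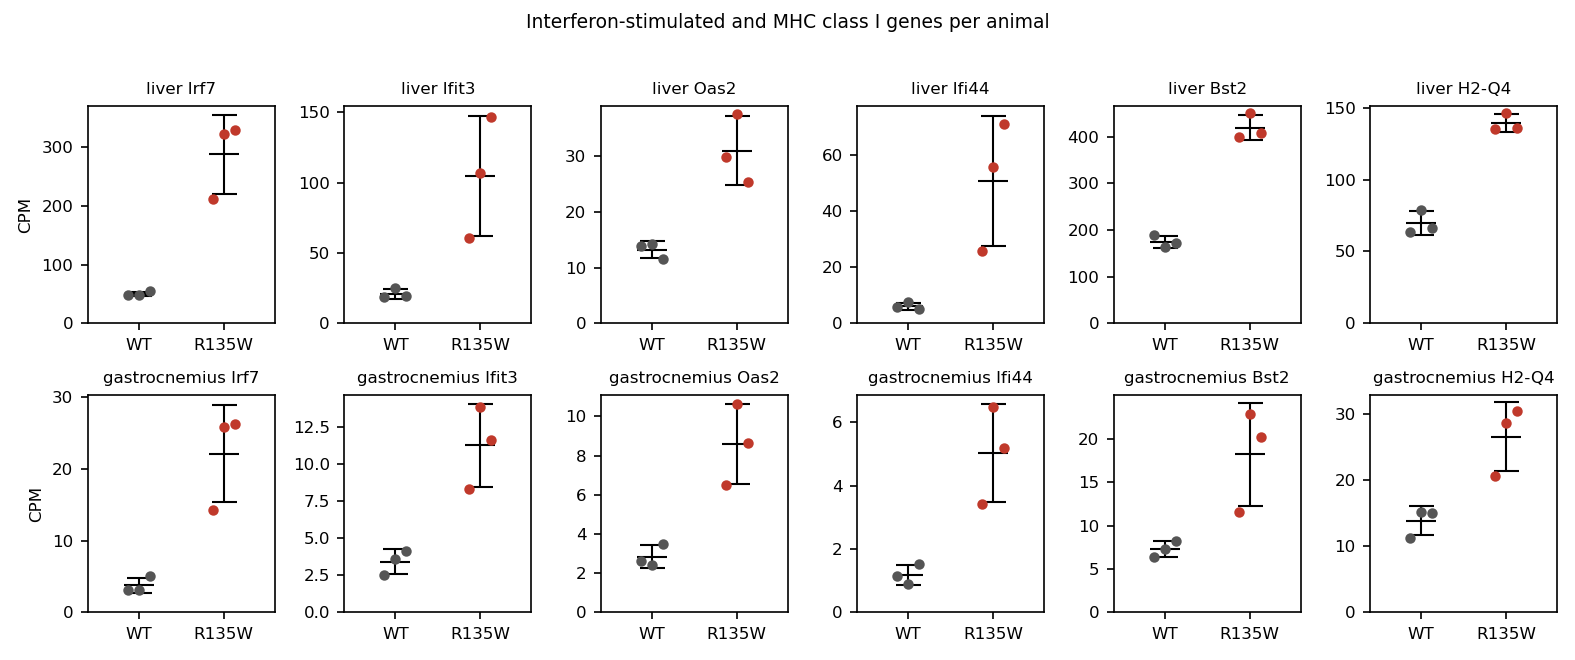
Levels in CPM of 6 interferon-stimulated or MHC class I genes in liver (top) and gastrocnemius (bottom); each point is 1 animal and the bars are mean ± SD with n = 3. In both tissues all R135W animals lie above all WT animals, for Irf7 at 287 against 50.3 CPM in liver and 22.1 against 3.75 CPM in muscle.

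MHC class I antigen presentation genes, which display peptides to cytotoxic T cells, rose for 10 of 18 members, and 15 adjusted over the list alone (adjusted p = 0.22 with an estimated correlation). H2-Q4 rose from 69.6 ± 8.20 to 139 ± 6.37 CPM and the immunoproteasome subunit Psmb8 changed by 1.01 (SE 0.15). H2-Q6 changed by 1.64 (SE 0.15) and H2-Q7 by 1.37 (SE 0.13), and their counts are identical to those of H2-Q8 and H2-Q9, with which they share exons. For NF-kB inflammatory genes 4 of 13 rose, and 9 adjusted over the list alone (adjusted p = 0.0824 with an estimated correlation): the NF-kB subunit genes Relb at 1.16 (SE 0.19) and Nfkb2 at 0.72 (SE 0.13), the monocyte chemokine gene Ccl2 at 2.03 (SE 0.34) and the adhesion molecule gene Icam1 at 0.74 (SE 0.13). Cell cycle genes rose for 4 of 17, and 9 adjusted over the list alone (adjusted p = 0.435 with an estimated correlation). Besides Cdc20 these were Mcm5 at 1.95 (SE 0.32), Mcm2 at 1.15 (SE 0.22) and Mcm6 at 1.07 (SE 0.21), subunits of the replicative helicase.

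Markers of immune cells stood higher in R135W liver, in the same animals as the called lists of interferon-stimulated, MHC class I, NF-kB and cell cycle genes. Macrophage markers had a median of 1.08, with 13 of 17 risen and 15 adjusted over the list alone (adjusted p = 0.184 with an estimated correlation). The pan-macrophage marker Emr1 rose from 10.3 ± 2.0 to 29.9 ± 3.79 CPM, Cd5l from 75.9 ± 17.7 to 211 ± 23.4 CPM, and the lysosomal marker Cd68 from 8.15 ± 1.38 to 18.9 ± 0.515 CPM. Inflammatory monocyte markers rose for 4 of 6, and 6 adjusted over the list alone, with a median of 1.24 (adjusted p = 0.0824 with an estimated correlation); Itgax, an integrin gene, rose from 1.38 ± 0.486 to 3.88 ± 0.328 CPM, and Ly6c2 changed by 2.07 (SE 0.29), S100a4 by 1.44 (SE 0.29) and Plac8 by 0.97 (SE 0.17). Dendritic cell markers rose for 2 of 10, and 4 adjusted over the list alone (adjusted p = 0.142 with an estimated correlation): Itgax again and Bst2, the tetherin gene, which is also in the interferon list. NK cell markers rose for 2 of 6, over all genes and adjusted over the list alone (adjusted p = 0.337 with an estimated correlation), namely the granzyme gene Gzmb at 1.56 (SE 0.33) and the receptor gene Klrk1 at 1.05 (SE 0.22). Medians were 0.72 for 7 B cell and plasma cell markers, 0.60 for 7 T cell markers and 1.11 for 5 neutrophil markers. None of these passed in edgeR, against 5, 4 and 3 at an unadjusted p under 0.05, 1, 0 and 2 in DESeq2, 0 in limma-voom, and 1, 1 and 3 adjusted over the list alone (adjusted p = 0.369, 0.341 and 0.507 with an estimated correlation). The T cell list lost its call without R135W 12 (adjusted p = 0.0607), R135W 5 (0.0876) or WT 9 (0.0527). Markers of other cell types were not called as lists: medians were 0.11 for endothelial cells, -0.06 for fibroblasts and stellate cells, 0.03 for cholangiocytes and -0.17 for hepatocytes. The smooth muscle, Schwann cell, adipocyte and erythroid lists lay between -0.25 and 0.25. The collagen and extracellular matrix list was called higher at a median of 0.36, with 3 of 22 members risen, and 5 adjusted over the list alone (adjusted p = 0.369 with an estimated correlation): Tgfb1, a fibrogenic cytokine, at 0.84 (SE 0.17), Col1a1 at 0.67 (SE 0.14) and Col4a2 at 0.50 (SE 0.10).

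Of the metabolic lists, camera called those of fatty acid oxidation, cholesterol synthesis and xenobiotic cytochromes P450 lower in R135W liver. It did not call glycolysis, at a median of 0.16 (adjusted p = 0.131), lipogenesis, at -0.12 (0.25), or gluconeogenesis, at -0.01 (0.343), though lipogenesis was called without R135W 5 (0.00478) or WT 6 (0.0124) and gluconeogenesis without R135W 12 (0.0321). Fatty acid oxidation genes and targets of the lipid-sensing receptor PPARA had a median of -0.46, with 30 of 31 members negative, 1 fallen and 15 adjusted over the list alone (adjusted p = 0.43 with an estimated correlation). Ppara itself, from the list of mitochondrial biogenesis regulators, fell from 335 ± 36.1 to 214 ± 21.9 CPM. The cholesterol synthesis list was called lower at a median of -0.35, with 24 of 25 members negative and 1 fallen, over all genes and adjusted over the list alone (adjusted p = 0.608 with an estimated correlation); this was the sterol reductase gene Hsd17b7 at -0.84 (SE 0.14). Xenobiotic cytochromes P450 had a median of -0.64 and 2 of 24 fallen, with 3 lower and 1 higher adjusted over the list alone (adjusted p = 0.358 with an estimated correlation); Cyp2c37 fell from 921 ± 112 to 437 ± 82.9 CPM beside Cyp17a1. Genes with sex-biased levels in liver had a median of -0.56 and 1 of 22 fallen, Sult3a1, with 3 lower adjusted over the list alone (adjusted p = 0.358 with an estimated correlation). The endoplasmic reticulum unfolded protein response list was called lower at -0.27 with 0 of 18 members past edgeR's test, 2 at an unadjusted p under 0.05, 2 in DESeq2 and 0 in limma-voom (adjusted p = 0.608 with an estimated correlation). Complex I nuclear subunits were called lower at -0.10 with 0 of 36 past edgeR's test, 5 at an unadjusted p under 0.05, and 0 in DESeq2 and in limma-voom (adjusted p = 0.703 with an estimated correlation). For both of these lists the unadjusted share lay below that of all tested liver genes, 2449 of 13935. The NRF2 antioxidant list was called higher at 0.20 with 1 of 15 risen, and 5 adjusted over the list alone (adjusted p = 0.608 with an estimated correlation). That member was the heme oxygenase gene Hmox1, from 14.8 ± 0.526 to 31.6 ± 4.01 CPM, whose product also serves heme breakdown in macrophages. Without R135W 12 the unfolded protein response, complex I and NRF2 lists were no longer called (adjusted p = 0.0754, 0.197 and 0.197), nor was the first without WT 9 (0.244), the second without WT 6 (0.17), or the last without R135W 5 (0.052) or WT 9 (0.0718).

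Circadian clock genes in liver included members that rose and members that fell. The activators Arntl, at 1.40 (SE 0.21), and Npas2, at 2.01 (SE 0.43), rose, while the output factors Tef, at -1.18 (SE 0.20), and Hlf, at -0.84 (SE 0.14), and the repressor Bhlhe41 fell. Of the 6 fits without 1 library, Arntl kept its call in 4, Hlf in 2, Tef and Bhlhe41 in 1 each and Npas2 in 0. Levels were low for Npas2 in WT, at 0.405 to 1.34 CPM, and for Bhlhe41 in R135W, at 0.275 to 0.436 CPM. The list was called lower with a median of -0.63, with 2 risen and 3 fallen of 18, and 2 and 8 adjusted over the list alone (adjusted p = 0.335 with an estimated correlation). For the 5 that passed, all WT animals lay apart from all R135W animals, WT 6 among them, as for all 457 genes called in liver. WT 6 stood apart from the other WT animals for several members that did not pass: its Dbp level in liver was 19.4 CPM, against 61.7 and 91.3 CPM in WT 8 and WT 9 and 6.05 to 19.9 CPM in R135W. Its Per3 level was 14.7 CPM, against 50.8 and 65.7 CPM in WT and 6.6 to 13.5 CPM in R135W. In muscle it had the lowest levels of the 6 animals for Dbp, at 30.6 CPM, and Per2, at 7.89 CPM.

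Lists tied to mitochondrial protein synthesis and its stress responses were not called in liver. Integrated stress response targets had a median of 0.11 with 0 of 31 past the test in edgeR, DESeq2 or limma-voom and 9 at an unadjusted p under 0.05. Psat1, of serine synthesis, stood at 1.24 (SE 0.29, adjusted p = 0.061) and the stress-response gene Nupr1 at 2.46 (SE 0.67, adjusted p = 0.0969). For mitochondrial aminoacyl tRNA synthetases, 0 of 17 passed in any of the 3 tools and 0 at an unadjusted p under 0.05, with a median of 0.06. The mitochondrial ribosomal proteins had a median of -0.08 (0 of 76 in the 3 tools, 3 unadjusted) and a list adjusted p of 0.0528 (0.78 with an estimated correlation). They were called lower without R135W 5 (adjusted p = 0.00936), R135W 7 (0.0178), WT 8 (0.0232) or WT 9 (0.0151), and not without R135W 12 (0.586) or WT 6 (0.343). Mitochondrial chaperones and proteases had a median of 0.00 (0 of 14 in the 3 tools, 1 unadjusted). Among 29 respiratory complex assembly factors Ndufaf4 alone fell, at -0.52 (SE 0.11), and the lists for complexes II with III, IV and V, mitochondrial translation factors and the tricarboxylic acid cycle lay between -0.11 and -0.07. The uncalled lists further held the following members past the test: Pkm of glycolysis at 0.86 (SE 0.17), the amino acid transporter Slc1a4 at 0.99 (SE 0.17) among pericentral genes, the tropomyosin gene Tpm3 at 0.53 (SE 0.12) and the mitophagy receptor gene Bnip3 at -0.76 (SE 0.15). For 0 members past edgeR's test stood MHC class II (1 unadjusted), serine and one-carbon synthesis (3), cytosolic aminoacyl tRNA synthetases (1), heat shock (1), p53 targets (5), immediate early genes (1), lipogenesis (2), gluconeogenesis (2), bile acid genes (3), acute phase proteins (5), periportal genes (2), growth hormone axis (2), sarcomere (1) and proteasome (1), with medians between -0.20 and 0.25; limma-voom called 0 in each and DESeq2 at most 2. Genes encoded by mitochondrial DNA were not analysed here.

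The liver count depends on single animals: it was 263 without R135W 12, 266 without R135W 5, 114 without R135W 7, 285 without WT 6, 104 without WT 8 and 84 without WT 9. DESeq2 called 772 genes, a fit with age as a covariate 274, and a fit of all 12 libraries together 1057.

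In gastrocnemius, the same question gave a smaller set. Interferon-stimulated and MHC class I genes rose here too, with 21 of 53 and 9 of 18 members past the test, and Irf7 rose from 3.75 ± 1.10 to 22.1 ± 6.78 CPM. Lower in R135W were the forkhead transcription factor gene Foxo1, from 72.2 ± 12.3 to 21.3 ± 4.44 CPM, and the glucocorticoid-inducible chaperone gene Fkbp5, from 107 ± 20.9 to 35.0 ± 10.8 CPM. Macrophage markers were not called, with a median of 0.13 over 11 members. By edgeR's test 121 of 13826 genes passed, 75 higher and 46 lower, and 34 of them changed at least 2-fold (23 higher, 11 lower). All 121 had R135W and WT libraries fully apart, as did 16.6% of tested genes, where chance gives 10%. At an unadjusted p under 0.05 stood 1595 of the 13826 genes, the background for unadjusted counts within lists.

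Of the 10 largest rises in muscle among named genes of at least 1 CPM in a group, 4 belong to the interferon-stimulated list: Irf7, Apol9b, Ifi44 and Ifit3. In this set, after Irf7 at 2.56 (SE 0.26, adjusted p = 0.00918), came Pydc3, a pyrin-domain gene, at 2.43 (SE 0.42), the apolipoprotein L gene Apol9b at 2.42 (SE 0.37) and Ifi44 at 2.09 (SE 0.27). The class I genes H2-Q6 and H2-Q8, with identical counts, changed by 1.99 (SE 0.30), H2-Q7 and H2-Q9, again identical, by 1.74 (SE 0.30), and H2-Q5 by 1.72 (SE 0.30). Ifit3, an antiviral RNA-binding protein gene, rose from 3.44 ± 0.844 to 11.3 ± 2.80 CPM.

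Among the largest falls in muscle, Tfcp2l1, a grainyhead-like transcription factor gene, fell by 1.80 (SE 0.16) to 4.58 ± 1.30 CPM and the centrosomal protein gene Cep85l from 61.7 ± 17.5 to 18.1 ± 3.61 CPM. Zbtb16, the gene of the zinc finger repressor PLZF, fell from 115 ± 34.5 to 56.6 ± 8.45 CPM. Genes of amino acid handling were Slc7a8, a neutral amino acid transporter gene, at -1.04 (SE 0.16), and Prodh, proline dehydrogenase, at -1.03 (SE 0.14). The others were Oacyl at -1.16 (SE 0.17), the methyltransferase gene Inmt at -1.06 (SE 0.19) and Fibin at -1.05 (SE 0.16).

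**Figure D2:**
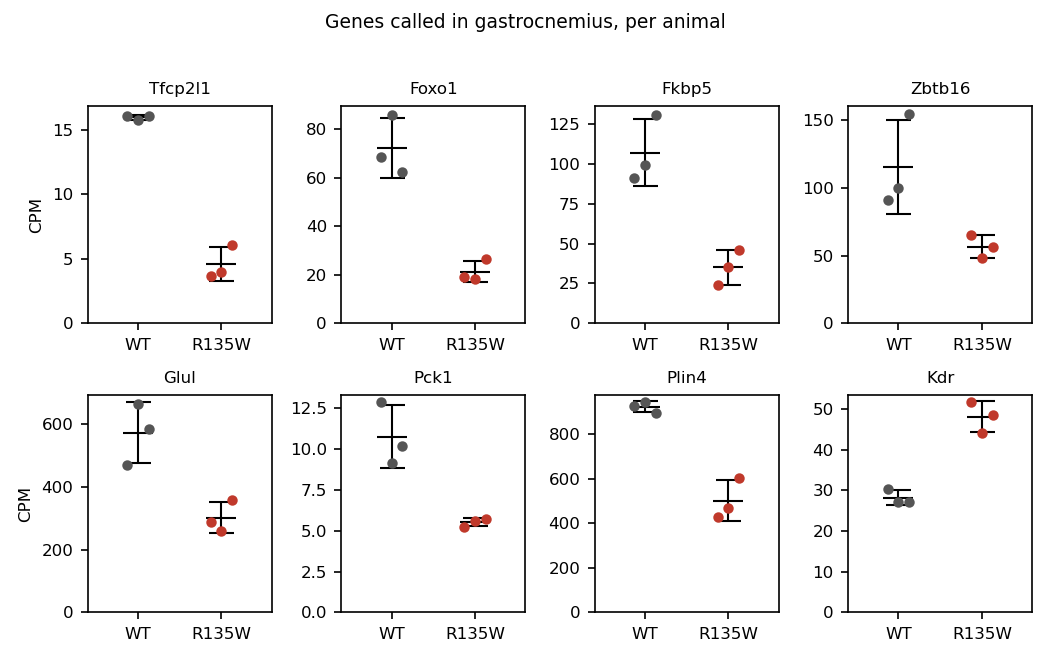
Levels in CPM of 8 genes that passed the test in gastrocnemius; each point is 1 animal and the bars are mean ± SD with n = 3. For Foxo1 the 3 R135W animals lie below the 3 WT animals, at 21.3 against 72.2 CPM, and Kdr lies higher, at 48.2 against 28.2 CPM.

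Camera called 14 of 55 lists in gastrocnemius, 9 higher and 5 lower. None held with an estimated correlation, under which 0 passed after adjustment and 5 at an unadjusted p under 0.05; fry called 2, of which 1 was among the 14. Of interferon-stimulated genes, 21 of 53 rose and 36 adjusted over the list alone, with a median of 0.77 (adjusted p = 0.404 with an estimated correlation); Oas2 rose from 2.85 ± 0.571 to 8.59 ± 2.06 CPM. MHC class I genes had 9 of 18 risen and 13 adjusted over the list alone (adjusted p = 0.404 with an estimated correlation), with H2-Q4 at 0.94 (SE 0.16) and H2-T22, which shares 93.2% of its exons with H2-T9, at 0.56 (SE 0.08). Guanylate binding proteins and immunity related GTPases had a median of 0.55, with Gbp3 alone risen, at 1.20 (SE 0.19), and 11 of 19 adjusted over the list alone (adjusted p = 0.668 with an estimated correlation). In the nucleic acid sensing list, at a median of 0.09, the double-stranded RNA sensor gene Ifih1 rose by 0.72 (SE 0.13), and 6 of 24 were higher and 1 lower adjusted over the list alone (adjusted p = 0.668 with an estimated correlation). NF-kB inflammatory genes were called higher at a median of 0.32 with 0 of 7 members past edgeR's test, 3 unadjusted and 0 in DESeq2 or limma-voom (adjusted p = 0.568 with an estimated correlation). Immune cell markers were sparse in muscle: Bst2, at 1.32 (SE 0.22), was the 1 of 6 dendritic cell markers that rose. The T, NK, B cell, monocyte and neutrophil lists had too few measured members. The sensing list lost its call without R135W 12, R135W 7 or WT 6 (adjusted p = 0.0869, 0.343 and 0.0919) and the NF-kB list without R135W 12 (0.0734).

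Endothelial markers were called higher in muscle at a median of 0.28, with 1 of 12 risen and 6 adjusted over the list alone (adjusted p = 0.366 with an estimated correlation); Kdr, the VEGF receptor gene, rose from 28.2 ± 1.80 to 48.2 ± 3.90 CPM. The extracellular matrix list was called higher at 0.31, where the membrane-bound metalloproteinase gene Mmp14 rose by 0.66 (SE 0.11), the 1 of 23 that passed over all genes and adjusted over the list alone (adjusted p = 0.668 with an estimated correlation); without WT 8 that list was not called (adjusted p = 0.123).

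Adipocyte markers were called lower in muscle, at a median of -0.31, with 1 of 10 fallen and 4 adjusted over the list alone (adjusted p = 0.404 with an estimated correlation). Their fallen member, the lipid droplet gene Plin4, went from 921 ± 24.6 to 500 ± 92.2 CPM, and 2 enzymes of lipid and glucose synthesis fell beside it: the desaturase gene Scd1 from 112 ± 24.6 to 68.5 ± 3.76 CPM and the gluconeogenic Pck1 from 10.7 ± 1.93 to 5.52 ± 0.253 CPM. The sterol hydroxylase gene Cyp27a1 changed by -0.54 (SE 0.10) and Glul, glutamine synthetase, by -0.93 (SE 0.14). Muscle atrophy genes were called lower at -0.20, with 2 of 17 fallen, Foxo1 and Bnip3, and 4 adjusted over the list alone (adjusted p = 0.516 with an estimated correlation). The slow fibre list was called lower at -0.25 with 0 of 13 past edgeR's test, 7 unadjusted, 1 in DESeq2, 0 in limma-voom and 1 adjusted over the list alone (adjusted p = 0.668 with an estimated correlation). The fast glycolytic fibre list was called higher at 0.10 with 0 of 13 in the 3 tools and 2 unadjusted, and the glycolysis list at 0.09 with 0 of 19 in edgeR and limma-voom, 1 in DESeq2, 3 unadjusted and 2 adjusted over the list alone; for both the adjusted p was 0.668 with an estimated correlation. Fatty acid oxidation genes, at -0.06 with 0 of 25 in the 3 tools and 4 unadjusted, and mitochondrial ribosomal proteins, at -0.03 with 0 of 76 in the 3 tools and 7 unadjusted, were called lower (adjusted p = 0.668 for each with an estimated correlation). Calls ended for slow fibre genes without R135W 5 (adjusted p = 0.142), for fast fibre genes without R135W 12 (0.177) or WT 9 (0.128), and for fatty acid oxidation without R135W 7 (0.321) or WT 6 (0.168). Glycolysis lost its call without R135W 12, R135W 5, WT 6 or WT 9 (0.177, 0.12, 0.0949 and 0.128), and mitochondrial ribosomal proteins without R135W 12, R135W 7, WT 8 or WT 9 (0.228, 0.0727, 0.115 and 0.0916).

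Among uncalled lists in muscle, integrated stress response targets had a median of -0.03 with 0 of 30 in the 3 tools and 3 at an unadjusted p under 0.05. Mitochondrial aminoacyl tRNA synthetases had a median of -0.08 with 0 of 17 in edgeR and limma-voom, 1 in DESeq2 and 4 unadjusted. Complex I, with 0 of 36 in the 3 tools and 2 unadjusted, lay at -0.03 (list adjusted p = 0.122), and was called without R135W 5 (0.0474), R135W 7 (0.0456) or WT 6 (0.0221). The lists for the other complexes, their assembly factors, mitochondrial translation and the tricarboxylic acid cycle lay between -0.05 and -0.02. In the endoplasmic reticulum unfolded protein response list edgeR called 1 of 18 members over all genes, the chaperone gene Dnajb9 at -0.36 (SE 0.07), and 2 adjusted over the list alone, with 3 unadjusted, 2 in DESeq2 and 0 in limma-voom. The sarcomere, muscle fibre, denervation, satellite cell, tendon, nerve and smooth muscle lists had medians between 0.04 and 0.12. They held 0 members past edgeR's test or limma-voom. At an unadjusted p under 0.05 stood 5 denervation genes, 3 each of satellite cell and smooth muscle genes, and at most 1 each in the rest. DESeq2 called 1 denervation gene. Camera called the tendon list without WT 9 (adjusted p = 1.41e-06) or R135W 5 (0.0351). It called muscle fibres without WT 8 (0.0019) or R135W 5 (0.0189) and nerve without WT 6 (0.00195). Satellite cells were called without R135W 5 (0.0351) and smooth muscle without WT 9 (0.0122).

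The muscle count was 47 without R135W 12, 106 without R135W 5, 21 without R135W 7, 38 without WT 6, 3 without WT 8 and 9 without WT 9. The excess of higher over lower genes turned round without R135W 12 (16 higher, 31 lower), WT 6 (11 and 27) and WT 8 (1 and 2). DESeq2 called 265 genes and a fit of all 12 libraries together 20.

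**Figure D3:**
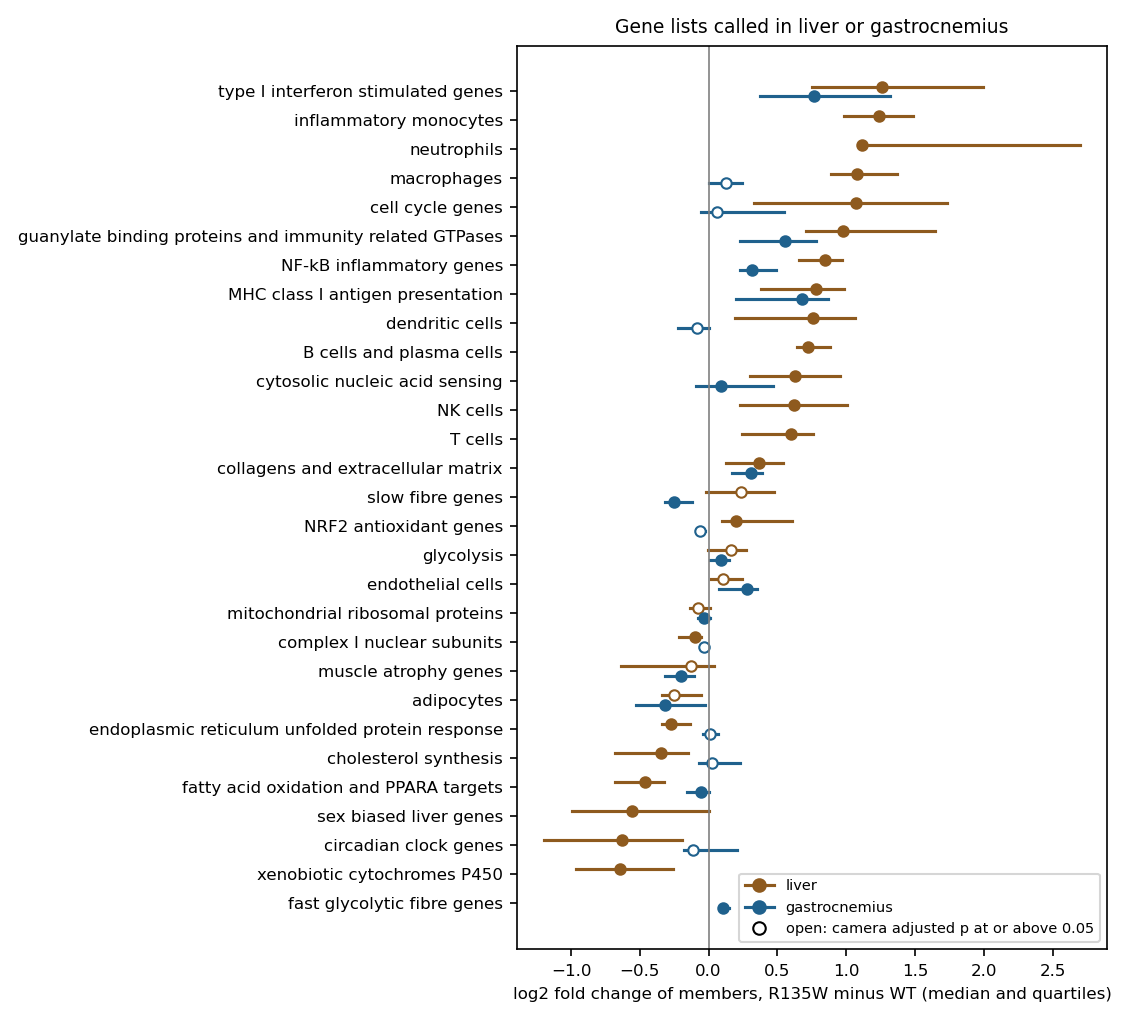
Median log2 fold change (R135W minus WT, horizontal axis) of the members of each list called in liver or gastrocnemius, with lines from the lower to the upper quartile; filled points passed camera's adjusted p of 0.05. Interferon-stimulated genes lie at 1.26 in liver and 0.77 in muscle, and macrophage markers at 1.08 and 0.13.

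The third question was whether the genotype effect differed between the tissues. Ifi27, an interferon-induced gene, differed most clearly: it rose by 1.91 (SE 0.12) in liver and stood at 0.11 (SE 0.07) in muscle. Slc7a8 went opposite ways, at 1.24 (SE 0.18) in liver and -1.04 (SE 0.16) in muscle, and Tfcp2l1 fell in muscle, at -1.80 (SE 0.16), and stood at 0.25 (SE 0.15) in liver. The effect was more negative in muscle than in liver for Sirpa, which encodes the receptor for CD47, the apoptotic cell receptor gene Axl, the kinase gene Syk, the semaphorin gene Sema4d and Hmox1, between -1.22 and -1.13 as gastrocnemius minus liver. By the interaction test 20 of 15414 genes passed, 5 with a more positive and 15 with a more negative effect in muscle, and 1534 at an unadjusted p under 0.05.

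Taking the animal as a replicate block, since both tissues came from the same animals, left 16 genes, of which 10 were among the 20. The gastrocnemius minus liver differences with adjusted p without and with the block were -1.80 (1.01e-05 and 0.00131) for Ifi27, -2.28 (0.00503 and 0.011) for Slc7a8, -2.04 (0.00503 and 0.011) for Tfcp2l1, -1.15 (0.00503 and 0.0409) for Sirpa and -1.19 (0.00703 and 0.011) for Axl. They were -1.13 (0.0104 and 0.0409) for Sema4d, -2.16 (0.0138 and 0.0157) for the DNA-sensor family gene Ifi205 and -1.13 (0.0184 and 0.0413) for Hmox1. The block ended the call of Ifi27l2a, at -0.98 (adjusted p = 0.0138 without and 0.0608 with it), and of Syk, at -1.22 (0.0274 and 0.0845).

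**Figure D4:**
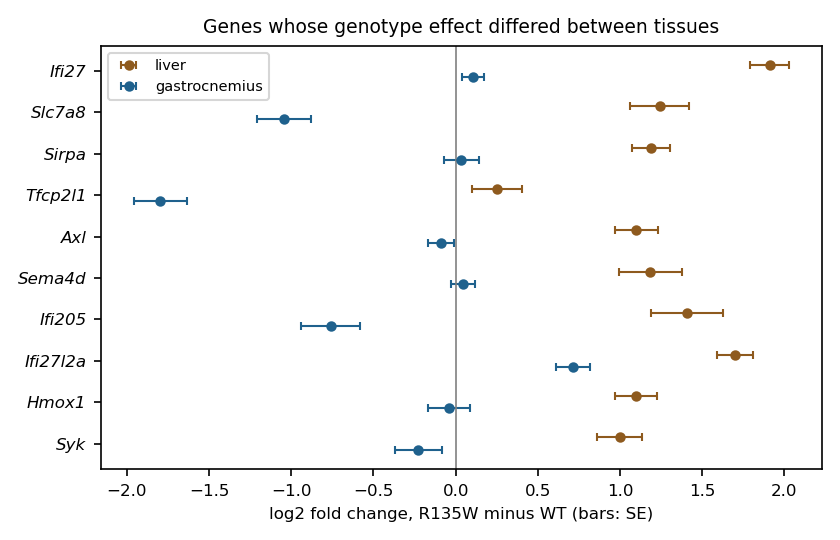
Log2 fold change (R135W minus WT, horizontal axis) in liver and gastrocnemius of the 10 named genes whose genotype effect differed between tissues; bars are SE of fits with 3 animals per group. Ifi27 lies at 1.91 in liver and 0.11 in muscle, and Slc7a8 at 1.24 and -1.04.

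Of 64 lists tested for the difference, camera called 16, 6 with a more positive and 10 with a more negative effect in muscle; 17 were called with the animal block, 14 of them among the 16. The balance turned to 9 and 7 without animal 5, 11 and 9 without animal 6, and 10 and 9 without animal 7. None held with an estimated correlation (6 at an unadjusted p under 0.05) and fry called 0 (7 unadjusted). Interferon-stimulated genes had a median difference of -0.45, with 2 of 55 members lower, Ifi27 and Ifi27l2a, and 3 adjusted over the list alone (adjusted p = 0.629 with an estimated correlation). Macrophage and inflammatory monocyte markers had median differences of -0.97 and -1.44, with 9 and 4 members lower adjusted over the list alone (adjusted p = 0.316 for each with an estimated correlation). MHC class I genes were not called, at -0.17 (adjusted p = 0.228), but with the animal block they were (0.0449), as were complex I subunits (0.0773 without and 0.00873 with it) and proteasome subunits (0.0557 and 0.0203). These 3 did not hold in the blocked fit with an estimated correlation (adjusted p = 0.653, 0.786 and 0.713). The block ended the calls of NF-kB inflammatory genes (adjusted p = 0.0488 without and 0.077 with it) and hepatocytes (0.000223 and 0.0583). Clock genes had a median difference of 0.53, with 7 members higher and 1 lower adjusted over the list alone (adjusted p = 0.316 with an estimated correlation), and cell cycle genes one of -0.72 with 3 lower adjusted over the list alone (adjusted p = 0.629 with an estimated correlation). The fatty acid oxidation and cholesterol synthesis lists stood at 0.38 and 0.40, with 0 members past the test over all genes or adjusted over the list alone (adjusted p = 0.629 for each with an estimated correlation). Hepatocyte markers stood at 2.48 and xenobiotic cytochromes P450 at 1.67 (adjusted p = 0.629 for each with an estimated correlation). The gastrocnemius library of animal R135W 12 held the most liver transcripts: its Alb level was 0.044% of the liver mean, against 0.000397% to 0.00833% in the other muscle libraries. Without that library these medians were -0.04 and 0.40, and neither list was called (adjusted p = 0.898 and 0.573). The cell cycle list lost its call without animal 9 (adjusted p = 0.0571).

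The number of genes called for the difference was 5 without animal 12, 1 without animal 5, 7 without animal 7, 6 without animal 6, 5 without animal 8 and 1 without animal 9, and 7 without the gastrocnemius library of animal 12 alone, a fit chosen after seeing the data. DESeq2 called 183 genes.

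The same genes rose in both tissues more often than independent lists would give. Of 12413 genes tested in both, 301 rose in liver and 68 in muscle, and 34 did so in both, where independence gives 1.65 (Fisher's exact test, two-sided p = 2.51e-37). Fisher's test takes genes as independent, but genes vary together and both tissues came from the same 6 animals. Its p-values here therefore overstate the evidence that 6 animals give. The 34 also count H2-Q6 and H2-Q8, and H2-Q7 and H2-Q9, as separate genes although their counts are identical. Interferon-stimulated genes among the 34 include Irf7, Ifi44, Ifit2, Ifit3, Oas2, Oasl2, Rsad2, Bst2, Rtp4 and Apol9a, the last at 3.64 (SE 0.57) in muscle, from a low level of 0.0651 CPM in WT. The 34 also hold the class I genes H2-D1, H2-T23 and H2-Q4 and the ubiquitin-like modifier activating gene Uba7. Lower in both were Sec24a, of the COPII vesicle coat, and Bnip3, 2 genes where independence gives 0.191 (Fisher's exact test, two-sided p = 0.0155); neither was called in both tissues in any of the 6 fits without 1 animal, where no gene was lower in both by edgeR. Slc7a8 was the 1 gene called in opposite directions. Across genes, which are not independent replicates, log2 fold changes correlated with r = 0.327. The shared count of 36 was 7 without animal 12, 44 without animal 5, 1 without animal 7, 2 without animal 6, 0 without animal 8 and 1 without animal 9, and 66 with DESeq2.

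**Figure D5:**
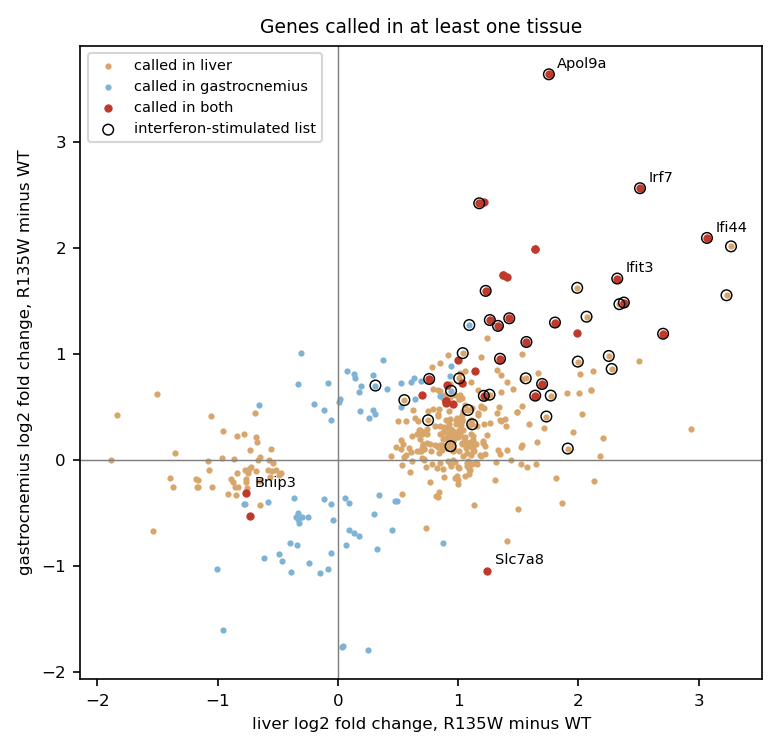
Log2 fold changes (R135W minus WT) in liver (horizontal axis) and gastrocnemius (vertical axis) of genes called in at least 1 tissue; circles mark the interferon-stimulated list. The 34 genes higher in both tissues lie at the upper right and Slc7a8 at the lower right.

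Genes close to Mars2 were compared with the rest of the genome, since an edited line can carry linked differences. Within 5 Mb, 3 of 58 tested genes (5.17%) were called in liver against 3.27% elsewhere (Fisher's exact test, two-sided p = 0.44). In gastrocnemius 0 of 61 were called by edgeR against 0.879% elsewhere, too low a share for the test to tell a difference among so few genes (Fisher's exact test, two-sided p = 1). At an unadjusted p under 0.05 stood 12 of the 61, against 1595 of all 13826 tested genes, and DESeq2 called 2 and limma-voom 0.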

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

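Of the tests below, the list contrasts, the clock correlation and the fit without the gastrocnemius library of animal 12 were chosen after the results were seen; the splits of the animals and the tests of the difference between tissues were planned.

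The genes and lists here stood out because the test of the difference between tissues passed for each. As gastrocnemius minus liver log2 values, Ifi27 stood at -1.80, Slc7a8 at -2.28, Tfcp2l1 at -2.04, Ifi205 at -2.16, Syk at -1.22, Axl at -1.19, Sirpa at -1.15, Sema4d and Hmox1 at -1.13 each, and Ifi27l2a at -0.976. With the animal as a block the adjusted p was 0.0608 for Ifi27l2a and 0.0845 for Syk, and below 0.05 for the other 8. Leaving out 1 animal at a time, 4 of these 10 kept their call without animal 12, 1 without animal 5, 6 without animal 7, 3 without animal 6, 4 without animal 8 and 1 without animal 9; Ifi27 kept it in all 6 fits.

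Lists whose members had the more negative effect in muscle were interferon-stimulated genes (median -0.451), guanylate binding proteins and immunity related GTPases (-0.617), cytosolic nucleic acid sensing (-0.355), NF-kB inflammatory genes (-0.391), serine, glycine and one-carbon synthesis (-0.575), NRF2 antioxidant genes (-0.271), p53 targets (-0.276), cell cycle genes (-0.718), macrophages (-0.969) and inflammatory monocytes (-1.44). The more positive effect in muscle belonged to the endoplasmic reticulum unfolded protein response (0.293), circadian clock genes (0.529), fatty acid oxidation and PPARA targets (0.383), cholesterol synthesis (0.404), xenobiotic cytochromes P450 (1.67) and hepatocytes (2.48). With an estimated correlation the adjusted p was 0.316 to 0.629 for these 16 lists. With the animal as a block NF-kB (adjusted p = 0.077) and hepatocytes (0.0583) were not called. Over genes tested in both tissues 12 lists were called, 11 of them among the 16, and NF-kB (adjusted p = 0.0507) and serine synthesis (0.0852) were not. Inflammatory monocytes, xenobiotic cytochromes P450 and hepatocytes had too few such genes to be tested. Over these genes the median was smaller in size for serine synthesis, at -0.127, and cell cycle genes, at -0.336. For macrophages it was -0.955. Calls were lost without 1 animal for NF-kB (adjusted p = 0.102 without 5, 0.118 without 6, 0.0858 without 7), NRF2 (0.11 without 12, 0.0555 without 5, 0.0655 without 9), serine synthesis (0.0883 without 5, 0.109 without 6), the unfolded protein response (0.129 without 12, 0.351 without 9) and cell cycle genes (0.0571 without 9).

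The first pattern weighed is the joint rise of interferon-stimulated genes and macrophage markers in R135W liver. A lower share of hepatocytes would raise markers of every other cell type alike, but the macrophage median exceeded that of endothelial, cholangiocyte and fibroblast markers by 1.04 on the log2 scale (1.08 against 0.03, one-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Whether more macrophages in the R135W pieces account for the interferon rise in liver is not settled. More macrophages alone would leave the interferon median at or below the macrophage median. It lay above by 0.186, not beyond the spread of the members (one-sided permutation p = 0.156), which is no support for that account. Of 55 interferon genes, 12 rose more than Marco, the marker with the largest change, but these are the top of the list. The alternatives cannot be told apart, since each cell's own level is not measured in whole tissue. In gastrocnemius the same contrast was 0.642 (0.77 against 0.13, one-sided permutation p = 0.00013), which argues against more macrophages as the source there. An effect of the genotype on interferon genes within cells stays open as a hypothesis in both tissues.

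The second pattern is the shift of clock genes in liver. A difference in time of day of sampling between the genotypes would move both tissues of an animal the same way. Over the 18 clock genes, which are not independent, log2 fold changes in muscle followed those in liver with Pearson's r = 0.509 (Spearman's rho = 0.426). The one-sided permutation p of 0.0159 is against no correlation, while all genes correlated at r = 0.327. Whether the clock genes exceed that was not tested. Of the 18, 12 had the same sign. In muscle the clock list was not called (median -0.11, camera adjusted p = 0.979), with 0 of 18 past edgeR's test and 6 unadjusted. Its difference between tissues, at a median of 0.529, was called at camera's preset correlation alone. A shared shift in time, of which the labels say nothing, is neither shown nor excluded by these values. An effect of genotype on the clock would look alike and was not tested. The median absolute change was 0.78 in liver and 0.20 in muscle. WT 6 lay on the WT side of every R135W animal for the 5 called clock genes in liver. It did so for all 457 genes called there, so this does not bear on its clock. Its liver Dbp, not called, lay within the R135W values at 19.4 CPM.

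The third pattern is the hepatocyte list in the difference between tissues, at 2.48. Without the gastrocnemius library of animal 12 it was -0.03688 and the list was not called (adjusted p = 0.898), as it was not without both libraries of animal 12 (0.933). The 11 markers had a median of 0.0405% of their liver level in that library, against 0.000505% to 0.00833% in the others. Liver RNA in that muscle library is a likely source, with no biological explanation tested, and the call of xenobiotic cytochromes P450 was lost as well (adjusted p = 0.573 without the library and 0.786 without animal 12).

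For other splits of the animals, 10 are possible, too few for a share under 0.05. Every split but the real one mixes the genotypes in both arms. A genotype effect would then widen the spread within arms and lower the counts, so these splits are no clean baseline for chance. The real split called 457 genes in liver, 121 in gastrocnemius, 20 for the difference and 36 shared, each the 1 split with a count as large, with 0 by edgeR as the highest of the others, on which no other tool was run; at an unadjusted p under 0.05 these counts were 2449, 1595, 1534 and 335, against at most 1472, 1097, 1629 and 51. The correlation between tissues was 0.327, against a highest other of 0.213, again with 1 split as large. Counts of called lists behaved otherwise: 22 in liver against a highest other of 23 (2 splits as large), 14 in gastrocnemius against 21 (5 splits) and 16 for the difference against 20 (2 splits). By the size of the median, 15 of the 22 liver lists, 7 of the 14 gastrocnemius lists and 11 of the 16 difference lists exceeded every other split. For interferon-stimulated genes the medians were 1.26 in liver against at most 0.71, and 0.77 in gastrocnemius against at most 0.64, and camera called this list in 9 and 6 of the other 9 splits. For liver macrophage markers the median was 1.08 against 0.45.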

How the results depend on the processing

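The fit without the gastrocnemius library of animal 12 alone and the list test over genes tested in both tissues were chosen after the data were seen; the other alternatives were planned. No named gene turned its sign between settings where it was called under either. The balance of directions did turn: in gastrocnemius from 75 higher and 46 lower genes to 16 and 31 without R135W 12, 11 and 27 without WT 6 and 1 and 2 without WT 8, and from 9 higher and 5 lower lists to 5 and 6 without R135W 12. For the difference, 6 lists higher and 10 lower became 9 and 7 without animal 5, 11 and 9 without 6 and 10 and 9 without 7. RLE size factors, limma-voom, no filter and a stricter filter gave 400 to 532 genes in liver and 96 to 172 in gastrocnemius, within 1.5 times of the 457 and 121 reported. DESeq2 gave 772 genes in liver, 265 in gastrocnemius, 183 for the difference and 66 shared, and the cause was not tested. With age as a covariate 274 genes passed in liver, and with all 12 libraries in 1 fit 1057 in liver and 20 in gastrocnemius, where the spread is pooled over both tissues; the cause was not tested. A minimum change of 2-fold left 263 and 34 by construction. The shared count at an unadjusted p of 0.05 was 335. For the difference, the animal block gave 16 genes, RLE 20 and no filter 27.

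With 1 library or animal left out, gene counts were lower in every fit except that of shared genes without animal 5. Leaving out 1 library gave 84 to 285 genes in liver (263 without R135W 12, 266 without R135W 5, 114 without R135W 7, 285 without WT 6, 104 without WT 8, 84 without WT 9) and 3 to 106 in gastrocnemius (47, 106, 21, 38, 3 and 9 in that order). Leaving out 1 animal gave 1 to 7 genes for the difference (5, 1, 7, 6, 5 and 1) and 0 to 44 shared genes (7, 44, 1, 2, 0 and 1), and leaving out the muscle library of animal 12 gave 7. With an arm of 2 animals, each gene's spread leans more on that of the others. Of 69 named genes called in liver, 19 kept their call in all 6 fits; 39 kept it without R135W 12, 43 without R135W 5, 30 without R135W 7, 47 without WT 6, 26 without WT 8 and 22 without WT 9. Of 35 in gastrocnemius 2 did, Foxo1 and Tfcp2l1, with 15, 25, 5, 14, 2 and 7 in that order. Across the other settings 451 of 483 values in liver, 214 of 245 in gastrocnemius and 38 of 40 for the difference kept their call and direction, and the rest kept the direction.

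Called lists numbered 22, 14 and 16 for liver, gastrocnemius and the difference. With an estimated correlation these were 0, 0 and 0, and with fry 10, 2 and 0; the cause was not tested. Leaving out 1 library or animal gave 21 to 26 lists in liver, 11 to 21 in gastrocnemius and 13 to 20 for the difference, the block 17, leaving out the muscle library of animal 12 17, and genes tested in both tissues 12. With 1 library or animal left out, 12 uncalled lists in liver, 13 in gastrocnemius and 9 for the difference were called in at least 1 fit, among them integrated stress response targets for the difference without animal 12 (adjusted p = 0.0241) or 6 (0.0243). The log2 fold change of Mars2 was not called under any setting. Leaving out 1 library it ranged from -0.12 (without R135W 12) to 0.28 (without WT 9) in liver, with -0.04 without WT 6, and from -0.39 (without R135W 5) to -0.24 (without R135W 12) in gastrocnemius. For genes near Mars2 Fisher's exact p was 1 with 2 Mb in liver and 0.693 with 20 Mb in gastrocnemius, with so few calls in reach that these tests decide little. Whether more depth would add calls was not tested. At levels such as those of Mars2 in liver, 48 to 120 counts, counting adds to the spread between animals.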

Other observations

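The list of other glucocorticoid-induced genes and its tests below were chosen after the results were seen.

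Several of the genes that fell in R135W gastrocnemius are known targets of the glucocorticoid receptor: Foxo1, Fkbp5, Zbtb16, Pck1 and Glul. Among 18 other glucocorticoid-induced genes, 14 had negative log2 fold changes in R135W gastrocnemius, with a median of -0.19. By edgeR's test 0 of them fell over all genes and 2 adjusted over the list alone, Lpin1, a phosphatidate phosphatase gene, at -0.41 (SE 0.09, adjusted p = 0.0722) and Klf9, a Krüppel-like factor gene, at -0.30 (SE 0.07, adjusted p = 0.101). The glucocorticoid-induced leucine zipper gene Tsc22d3 stood at -0.50 (SE 0.22, adjusted p = 0.43).

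A candidate explanation, as a hypothesis, is lower glucocorticoid signalling in R135W muscle, which could also come with a different time of day. Camera gave an unadjusted p of 6.27e-05 for the list with its preset correlation, but 0.234 with the estimated correlation of 0.505, and fry gave 0.248. The hypothesis therefore cannot be told apart from joint variation of these genes between 6 animals. In liver the list had a median of -0.25, with camera p = 0.0205 at the preset and 0.366 with the estimated correlation.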
